A study of Mus musculus with 4 samples.

How the data were processed

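RNA from mouse colon was measured on 4 Affymetrix whole-transcript arrays, 1 for each combination of 2 genotypes and 2 tissues. Per the labels' protocols, total RNA was extracted with Trizol from normal colon and from colon tumours of C57BL/6 mice aged 3 months, and 400 ng were labelled with biotin. All mice carried the ApcF/+ genotype with the label CDX2, whose meaning the labels do not spell out, and were either Dmt1+/+ (wild-type here) or Dmt1F/F (F/F here). By convention F marks an allele flanked by loxP sites. The series' design text names 7 wild-type and 4 F/F animals. How the animals map to the arrays, and whether RNA was pooled, is not given in the sources used here.

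The values are log2 signals as deposited by the authors, 1 per probe set, made with RMA in the oligo package per the submitters' processing notes, which give no version of either. RMA corrects the background of each array, forces the arrays to a common distribution of probe intensities and summarises the probes of a probe set. It therefore removes any difference between arrays in total signal, and gives no detection call and no error for a single value. The table holds 41345 probe sets, whose log2 medians were 4.31, 4.27, 4.34 and 4.34 on the wild-type normal, F/F normal, wild-type tumour and F/F tumour arrays. No column of another sample was present (0 columns).

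Probe sets were named from the platform's annotation: 23521 had exactly 1 gene, 1814 had several and 16010 were unnamed in it. Gene IDs of 23328 of the single-gene probe sets matched the RefSeq table of mouse assembly GRCm38.p6, which gave the symbols used here, and 193 kept the annotation's own symbol. No coordinates were used. Of the 22180 genes, 1082 had more than 1 probe set, and the probe set with the highest mean was taken. A gene was kept if its highest value on the 4 arrays reached the median level of all genes (log2 4.67), which left 12060 genes. This level stands in for background, so a difference with 1 array below it understates the change, and one with both arrays below it is uncertain in size and direction. Probe sets of gene families with near-identical members (Defa, Mptx, Reg3, Cyp2c, Hsd3b, Ces1) may take signal from each other's transcripts, and their values are uncertain as to the member.

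With 1 array per group, a comparison of 2 arrays is a difference of 2 log2 values with no replicate check, and no p-value across genes is given. The number of arrays limits the precision of every value. Genes were counted at a log2 difference of 1 or more, which is 2-fold. For 37 gene lists fixed before the data were examined (744 members, 564 kept), the median difference of a list was placed among those of 10000 random lists of the same size, matched on mean level in 20 bins. A list was described as standing apart at or beyond the 2.5th or 97.5th percentile. This percentile describes these arrays and is no test of the conditions. The 34 lists with at least 5 kept genes covered iron transport and storage, iron-sulfur and heme synthesis, Wnt beta-catenin targets, stem cells, G2/M, G1/S, JAK-STAT3, ribosome biogenesis, colonocytes, goblet, enteroendocrine, tuft and Paneth cells, neutrophils, macrophages, T and NK cells, B and plasma cells, cytokines, interferon response, MHC class II, fibroblasts, smooth muscle, enteric neurons and glia, endothelium, adipocytes, squamous epithelium, distal and proximal position, hypoxia, fatty acid oxidation, oxidative phosphorylation, p53 targets, ion transport and housekeeping genes. The other 3 lists, erythroid cells, exocrine pancreas and sex-linked genes, had too few kept genes for a percentile.

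One model was fitted over the 4 arrays with limma (version 3.58.1 in R 4.3.3), with tissue and genotype as additive terms, eBayes with a trend, and Benjamini-Hochberg adjustment at 0.05 over the 12060 genes. It has 1 residual degree of freedom, the tissue by genotype term, moderated with a prior of 3.4 degrees of freedom. A gene passes for tumour against normal colon where its mean difference over both genotypes is large against the moderated residual. A call therefore does not show that the difference was of like size in both genotypes. Both tissues of a genotype may come from the same animals, so the genotype term does not measure the spread between animals. Adjusted p-values in the text are limma's from this model, with the fitted log2 difference and its standard error (SE). Counts for a list are also given adjusted over the list alone, with no adjustment across the lists. The fit was tested on simulated data for tumour against normal over both genotypes with 12060 genes: of 50 genes changed at each size, 54% were recovered at log2 1, 90% at log2 2, 100% at log2 3 and 98% at log2 4, with 12 false among 183 calls. The simulated noise was drawn independently for each array from the fitted prior, with no genotype effect. Recovery therefore rests on the model's own assumptions and does not show that the adjusted p-values hold for these arrays.

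The text names Slc11a2 (the gene of DMT1), Apc, Cdx2, Cdk1, Stat3 and Jak1; per comparison of 2 arrays the 10 genes with the largest positive and the 10 with the largest negative difference (5 for the difference of the tumour effects), leaving out unnamed transcripts, olfactory and vomeronasal receptors and immunoglobulin and T cell receptor segments; and the 2 highest and 2 lowest members of each list described, or some of them. This rule was fixed before the data were examined. Genes named outside it are said to be so. Alternatives fixed at the same time were cyclic loess, quantile normalization over the kept genes, centring each array on its median, no filter on level, a filter on the mean level, the mean of a gene's probe sets, thresholds of 1.5-fold and 3-fold, unmatched random lists, lists without shared members, and limma without the trend, with robust eBayes, without the filter or after cyclic loess. The other genotype's normal array as baseline was added after seeing the data. Python 3 scripts used pandas, NumPy and SciPy.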

Results

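The series profiled gene expression in normal colon and colon tumours of ApcF/+ mice that were wild-type or F/F for Dmt1, the gene of an iron importer with the symbol Slc11a2. Apc is the tumour suppressor whose loss activates Wnt signalling in the colon. There were 4 arrays, 1 each for wild-type normal colon, F/F normal colon, wild-type tumour and F/F tumour, so no group had a replicate and each difference between 2 arrays stands without a measure of its error. Over all probe sets, Pearson correlations were 0.982 between the normal arrays, 0.986 between the tumour arrays, 0.963 between wild-type normal colon and tumour, and 0.965 between F/F normal colon and tumour. These are across probe sets, which are not independent replicates.

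Slc11a2 was at log2 6.51 in wild-type normal colon and 6.13 in F/F normal colon, and at 6.64 in wild-type tumour and 6.19 in F/F tumour. The F/F array was lower by a log2 difference of -0.38 in normal colon and -0.45 in tumour, and 9.3% and 5.6% of the 12060 genes had a difference as low or lower. In the additive model the genotype difference was -0.41 (SE 0.12, adjusted p = 0.564, lower in both F/F arrays). The direction follows the genotype labels, but which part of the gene the probe set covers was not examined here, so the size of the difference does not measure the extent of deletion. Apc differed little between genotypes, by 0.17 in normal colon and -0.10 in tumour.

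The tumour of Dmt1 wild-type mice was set against normal colon of the same genotype to ask what separates the tumours from normal colon. Mptx2, a mucosal pentraxin, was higher by 4.94, the lipase-related Pnliprp1 by 4.90, the Wnt inhibitor Wif1 and the metallothionein Mt4 by 4.61, the transcription factor Prox1 by 4.56, the adenylate cyclase Adcy8 by 4.54 and the lipoxygenase Alox12 by 4.48. Erich3 and the defensin Defa24, a product of Paneth cells, the antimicrobial cells of the small intestine, were higher by 4.35 and the lysozyme Lyz1 by 4.32. Among lower genes, the lipid transporter Abca12 differed by -5.29, Cyp2c65 by -5.03, the fatty acid binding protein Fabp2 by -4.92, Cyp2c55 by -4.65 and the sulfate transporter Slc13a1 by -4.53. Hsd3b3 (-4.38), Aldh1a1 (-4.30), Tmigd1 (-4.20), Dpep1 (-4.10) and the goblet cell product Retnlb (-4.06) followed.

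In this comparison the Wnt target list had a median of 2.79 over 21 genes, above all 10000 random lists, and 20 of its genes were higher by 2-fold or more. The list medians of inflammatory cytokines and chemokines (2.35 over 20 genes), Paneth cells (2.19 over 11) and neutrophils (1.73 over 14) were also high, with differences of 3.99 for the metalloproteinase Mmp10, 3.92 for the cytokine Il1a and 3.42 for Retnlg. Proliferation lists were higher by less: 0.62 for G2/M and mitosis (29 genes), 0.58 for G1/S and DNA replication (26 genes) and 0.76 for ribosome biogenesis (19 genes). The medians of absorptive colonocytes (-1.34 over 28 genes), enteroendocrine cells (-1.39 over 12), smooth muscle (-1.42 over 18), enteric neurons and glia (-1.35 over 7), adipocytes (-1.04 over 10), goblet cells (-0.82 over 19) and fatty acid oxidation (-0.89 over 16) were low. Markers of position along the colon moved with them: the distal list, of posterior Hox genes, had a median of 1.14 (7 genes) and the small intestine and proximal list -1.14 (11 genes). Across 21 Hox genes, the distal list included, the difference had a rho of 0.661 with paralog number here and 0.610 in F/F mice. The labels give no position for any piece. Different positions of tumour and normal pieces therefore cannot be told apart from tumour changes, in either genotype or in limma's tumour calls. Intestinal stem cells (0.91), macrophages (0.52), endothelium (0.48) and fibroblasts (0.42) were higher, and ion transport (-0.78), tuft cells (-0.57), oxidative phosphorylation (-0.56), interferon response (-0.55), T and NK cells (-0.52), MHC class II (-0.47) and hypoxia (-0.23) lower. The JAK-STAT3 median of 0.35 stood apart at the 98.9th percentile, while those of iron transport and storage (0.15), iron-sulfur and heme synthesis (-0.15), squamous epithelium (0.49) and B and plasma cells (-0.27) did not stand apart. In total 791 genes were higher and 640 lower by 2-fold or more, 55.3% of them higher, and 43.7% were higher with each array centred on its median, which shifted the median of all genes by -0.12 from 0.08. Of 34 lists, 13 stood apart above random lists and 15 below. Lists of genes drawn at random would give 1.7 in all. Genes of a list can move together and some lists share genes, so this count is no test.

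The same comparison in Dmt1 F/F mice asked whether tumours of that genotype differ from normal colon in the same genes. Pnliprp1 (5.90), Lyz1 (5.15), Wif1 (5.02), Prox1 (4.80), Adcy8 (4.23) and the Wnt deacylase Notum (4.22) were again among the highest, with the metalloproteinases Mmp13 (5.13) and Mmp10 (4.77) and the proteoglycan Spock2 (4.41). The posterior homeobox gene Hoxd13 was higher by 5.33, from a log2 level of 3.02 in F/F normal colon, where wild-type normal colon had 6.86. The lowest were the transcription factor Osr2 (-4.77), the bile acid transporter Slc10a2 (-4.73), the carbonic anhydrase Car3 (-4.64), Abca12 (-4.39), Cyp2c65 (-4.32), Ces1g (-4.18), Slc13a1 (-4.10), Hsd3b3 (-4.07), the peptide Nts (-4.03) and the alkaline phosphatase Alpi (-4.00).

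By list, the F/F tumour had medians of 2.65 for Paneth cells, 2.05 for Wnt targets, with 15 of 21 genes higher by 2-fold or more, 1.45 for distal position, 1.31 for cytokines and chemokines and 0.76 for neutrophils. The B and plasma cell list stood at 1.12 over 14 genes, led by Cd79a (2.74) and the complement receptor Cr2 (2.69), where the wild-type comparison gave -0.27. G2/M and mitosis had a median of 0.57, G1/S 0.35, ribosome biogenesis 0.53, macrophages 0.94, stem cells 0.80, endothelium 0.71 and fibroblasts 0.58. Low medians were those of adipocytes (-1.77), proximal position (-1.64), enteroendocrine cells (-1.08), fatty acid oxidation (-0.89), smooth muscle (-0.64), absorptive colonocytes (-0.56), interferon response (-0.50), oxidative phosphorylation (-0.46), goblet cells (-0.31) and T and NK cells (-0.29). Iron transport and storage (0.005) and JAK-STAT3 (0.14) did not stand apart. There were 721 genes higher and 460 lower by 2-fold or more, 61.0% of them higher, and 51.9% after quantile normalization. With the wild-type normal array as baseline, an alternative chosen after seeing the data because the normal arrays differed in position genes, the counts were 482 and 253.

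**Figure D1:**
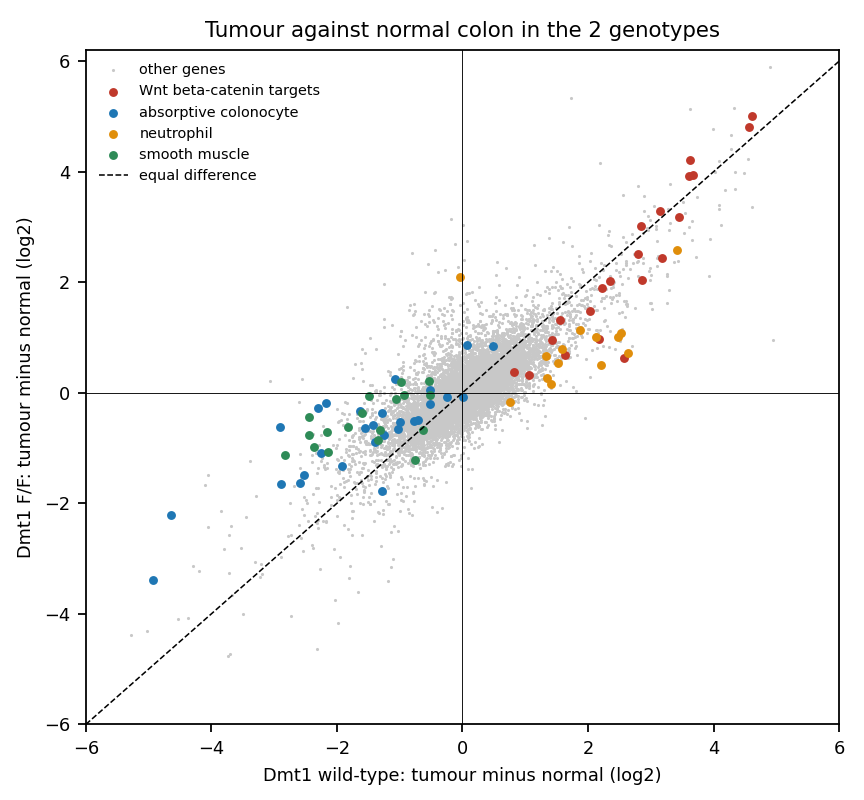
Tumour minus normal colon (log2) in Dmt1 wild-type mice on the horizontal axis and in F/F mice on the vertical axis, 1 point per gene for 12060 genes, with 4 gene lists in colour and a dashed line of equal difference. Of 21 Wnt targets, 14 lie below the line (medians 2.79 and 2.05), while 13 of 14 neutrophil genes lie below it (medians 1.73 and 0.76) and 26 of 28 colonocyte genes above it (-1.34 and -0.56).

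Between these comparisons, which share no array, 439 genes were higher by 2-fold or more in both genotypes against 47.3 for independent lists, 311 were lower in both against 24.4, and 6 went in opposite directions against 68.4. The differences correlated across genes with Pearson's r of 0.791 and Spearman's rho of 0.739; genes are not independent replicates. The 4 arrays were normalized together by the authors.

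Over both genotypes, limma called 1331 genes that rose in tumour and 992 that fell. The colon homeobox factor Cdx2 fell by 2.33 on the log2 scale (SE 0.16, adjusted p = 0.00715), lower in both tumour arrays. The mitotic kinase Cdk1 rose by 0.75 (SE 0.13, adjusted p = 0.0307), higher in both tumour arrays. Stat3 differed by 0.25 (SE 0.12, adjusted p = 0.194), Jak1 by -0.04 (SE 0.11, adjusted p = 0.814), Apc by -0.04 (SE 0.13, adjusted p = 0.855) and Slc11a2 by 0.10 (SE 0.12, adjusted p = 0.595). After cyclic loess the counts were 1059 and 1225, so that the share of calls that rose was 46.4% and not 57.3%.

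Of the 21 Wnt targets, 17 rose and none fell (21 rose adjusted over the list alone), among them the stem cell receptor Lgr5 by 3.32 (SE 0.13, adjusted p = 0.00349), while Ccnd1 (0.60, adjusted p = 0.0648) and Ephb3 (0.69, adjusted p = 0.0921) did not pass. Of 15 stem cell genes, 8 rose and 1, Prom1, fell by 1.17 (10 and 2 adjusted over the list alone). In G2/M and mitosis 16 of 29 genes rose, with Plk1 at 0.80 and Tpx2 at 0.88, and none fell (27 and 0 adjusted over the list alone). In G1/S 8 of 26 rose, with the helicase subunit Mcm3 at 0.99 and the polymerase Pole at 0.95 (13 and 1 adjusted over the list alone). Ribosome biogenesis had 10 of 19 genes that rose, with Nop56 at 1.15 (16 and 0 adjusted over the list alone).

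The JAK-STAT3 list was divided: 6 of 25 genes rose and 2 fell (7 and 3 adjusted over the list alone). Lipocalin Lcn2 rose by 3.55 (SE 0.16), the cytokine Il11 by 1.66 (SE 0.34) and the receptor Osmr by 1.03 (SE 0.16), whereas the antimicrobial lectins Reg3b and Reg3g fell by 3.16 (SE 0.20) and 2.65 (SE 0.11). Of 26 genes of iron transport and storage, 6 rose and 3 fell (9 and 3 adjusted over the list alone). Ceruloplasmin, Cp, a copper ferroxidase, rose by 1.97 (SE 0.13), the metalloreductase Steap2 by 1.17 (SE 0.21) and the heme and folate carrier Slc46a1 by 1.38 (SE 0.14). The iron exporter ferroportin, Slc40a1, fell by 0.82 (SE 0.11), and its partner ferroxidase hephaestin, Heph, fell by 1.22 (SE 0.18). In iron-sulfur and heme synthesis none of 17 genes rose and 3 fell (0 and 3 adjusted over the list alone).

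Among epithelial lists, 16 of 28 colonocyte genes fell and none rose (19 and 1 adjusted over the list alone), with Fabp2 at -4.15. For goblet cells 7 of 19 fell (10 adjusted over the list alone), with Spdef, a goblet cell factor, at -1.41. For enteroendocrine cells 8 of 12 fell, with somatostatin, Sst, at -2.20, and 1, Pyy, rose by 1.35 (8 and 1 adjusted over the list alone). In tuft cells Avil rose by 2.87 and the other 5 genes did not pass (1 rose and 1 fell adjusted over the list alone). In Paneth cells 8 of 11 rose, with Lyz1 at 4.74 and the phospholipase Pla2g2a at 3.17 (9 and 1 fell adjusted over the list alone). Of the metabolic lists, 15 of 16 genes of fatty acid oxidation fell, with Pdk4 at -1.31 (15 adjusted over the list alone), and 12 of 24 of oxidative phosphorylation fell, with Uqcrfs1 at -0.87 (16 adjusted over the list alone). Ion transport genes were mixed, 2 rising and 6 falling of 22 (4 and 8 adjusted over the list alone).

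Among other cell types, 12 of 20 cytokine and chemokine genes rose, with Mmp10 at 4.38, and 1, Ccl9, fell by 0.75 (14 and 1 adjusted over the list alone). Neutrophil genes rose in 3 of 14 cases, with Retnlg at 3.00 (9 adjusted over the list alone), and macrophage genes in 5 of 16, with Lyz2 at 1.15 (13 adjusted over the list alone). For T and NK cells 4 of 13 fell, with the granzyme Gzma at -2.46, and 1, Il7r, rose by 1.06 (6 and 1 adjusted over the list alone). Interferon response genes fell in 7 of 21 cases, with Ifit1 at -1.63, while 1, Cxcl9, rose by 1.25 (12 and 2 adjusted over the list alone). Fibroblast genes rose in 9 of 18 cases, with fibronectin, Fn1, at 2.11, and 1, Dpt, fell by 1.16 (9 and 2 adjusted over the list alone). In smooth muscle 6 of 18 fell, with Pln at -1.98 (10 adjusted over the list alone), and in adipocytes 5 of 10, with Pparg at -1.97 (7 adjusted over the list alone). Endothelial genes rose in 4 of 13 cases, with the cadherin Cdh5 at 1.19 (8 adjusted over the list alone); 1 of them, Prox1, is also a Wnt target. In neurons and glia the receptor Ret rose by 0.78 and the other 6 did not pass (1 rose and 5 fell adjusted over the list alone). No gene of the B and plasma cell list (14) or the MHC class II list (8) passed, also adjusted over the list alone.

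For position, 3 of 7 distal genes rose, with Hoxd11 at 1.81 and Hoxb13 at 1.91 (5 adjusted over the list alone), and 6 of 11 proximal genes fell, with Osr2 at -4.25, while 1, Onecut2, rose by 3.08 (7 and 1 adjusted over the list alone). Where the pieces were taken and the tumour itself cannot be told apart in these calls. Hypoxia genes were mixed, 5 rising and 3 falling of 20 (5 and 7 adjusted over the list alone), as were p53 targets, 3 and 1 of 14 (3 and 2 adjusted over the list alone), and housekeeping genes, 1 and 1 of 11 (1 and 1 adjusted over the list alone).

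**Figure D2:**
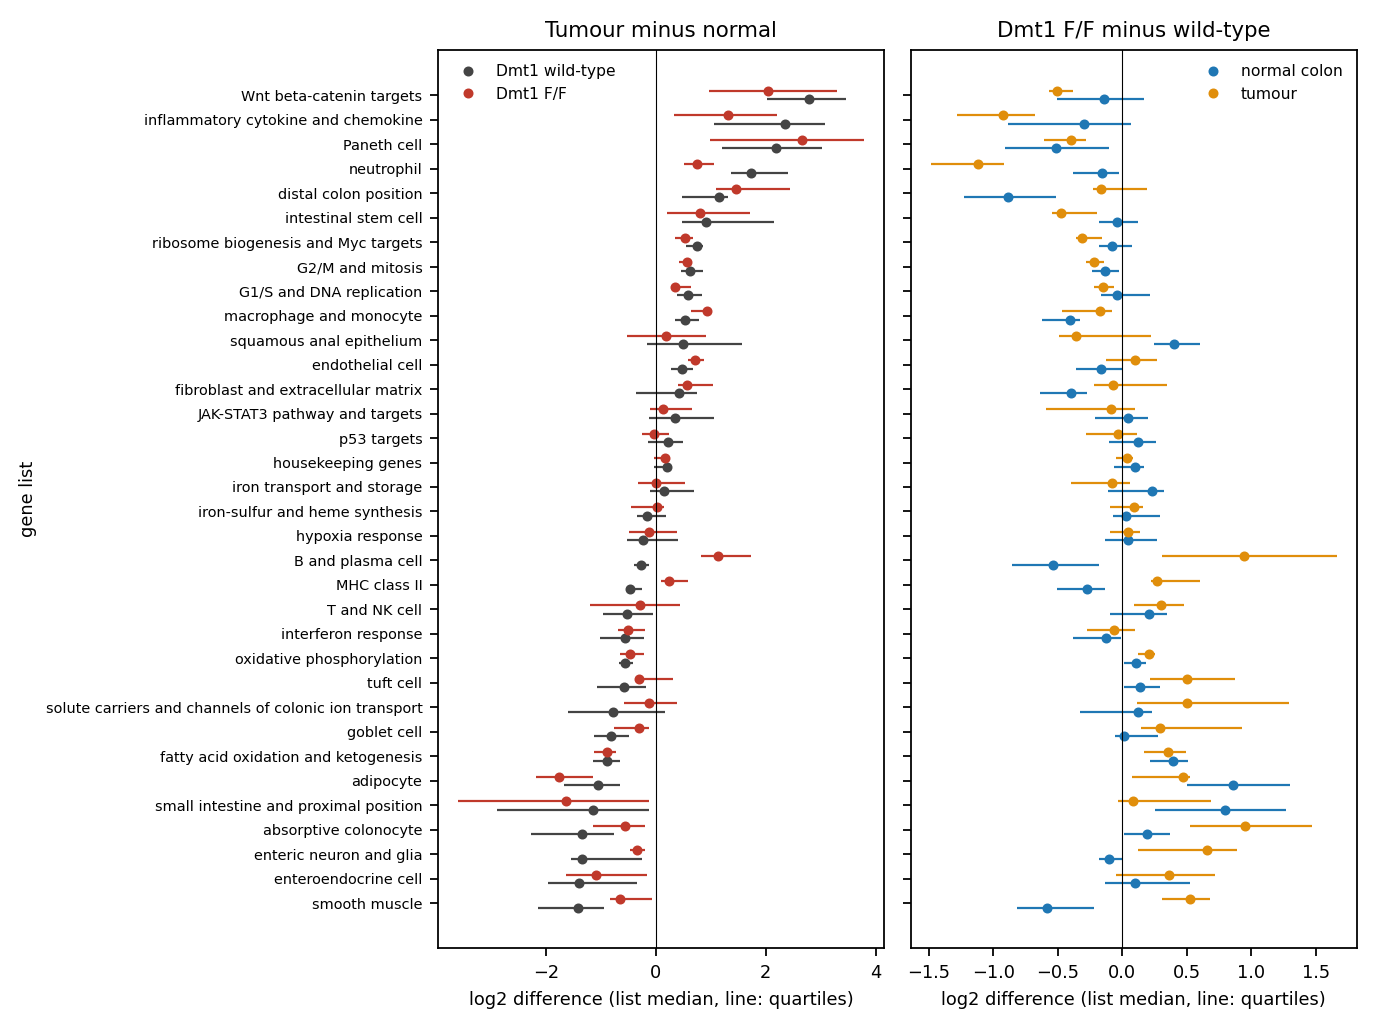
Median log2 difference of each of 34 gene lists (points) with the quartiles of its genes (lines), for tumour minus normal colon in each genotype on the left and for F/F minus wild-type in each tissue on the right; the panels have different scales. In the left panel Wnt targets are at 2.79 and 2.05 and Paneth cells at 2.19 and 2.65, and in the right panel the neutrophil list is at -1.12 and the colonocyte list at 0.95 in tumour against -0.16 and 0.19 in normal colon.

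F/F and wild-type normal colon were compared to ask what the Dmt1 genotype changes outside the tumours. The transferrin receptor Tfrc, whose mRNA is stabilised when cells are short of iron, was higher in F/F normal colon by 0.55, and the heme oxygenase Hmox1 by 0.52, while Cp (-0.72) and the iron hormone Hamp (-0.72) were lower. The iron list as a whole had a median of 0.23 over 26 genes, at the 99.9th percentile of random lists, and at the 81.7th without the filter on level. The largest single differences lay elsewhere. The sugar phosphate transporter Slc37a2 (2.18), Car3 (2.18), the disaccharidase Sis (2.10), Slc10a2 (1.98), St3gal5 (1.95), Ugt2b5 (1.90), the lipoprotein lipase Lpl (1.86), Ces1g (1.85), Clec2e (1.77) and the bile acid transporter subunit Slc51a (1.76) were higher in F/F. Hoxd13 (-3.84), Casp14 (-2.82), the phospholipases Pla2g4c (-2.63) and Pla2g2a (-2.52), Mmp13 (-2.11), St8sia5 (-2.05), Tgm3 (-1.91), Ccn3 (-1.77), Sval1 (-1.67) and Ctse (-1.65) were lower.

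Position markers separated the normal arrays. The distal list had a median of -0.88 in F/F, below all random lists, with Hoxb13 at -1.25, and the proximal list 0.80, above all of them. Adipocyte genes (0.86 over 10 genes, Retn at 1.43) and fatty acid oxidation (0.39 over 16, Cpt1a at 0.65) were higher. Smooth muscle (-0.58, the filament gene Des at -1.06), B and plasma cells (-0.53), Paneth cells (-0.51), macrophages (-0.41, Msr1 at -0.98), fibroblasts (-0.40, Fn1 at -1.08), cytokines (-0.29), MHC class II (-0.27, H2-Aa at -0.67) and interferon response (-0.13, Cxcl9 at -1.20) were lower. The colonocyte median was 0.19 and the squamous epithelium median 0.40 (6 genes, Krt14 at 0.88). G2/M and mitosis was at -0.13, with Cenpe at -0.39, Wnt targets at -0.14, with Mmp7 at -1.12, G1/S at -0.04 and JAK-STAT3 at 0.04, with Lcn2 at -1.42. The Wnt percentile of 0.40 became 3.71 after quantile normalization and 6.88 with the mean of the probe sets. Cdx2 was higher by 0.92, and Cdk1 (-0.10), Stat3 (0.12) and Jak1 (-0.05) differed little. In all 86 genes were higher and 109 lower by 2-fold or more.

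F/F and wild-type tumours were compared to ask what the Dmt1 genotype changes in the tumour. The largest negative differences in the F/F tumour were those of Mptx2 (-4.13), the cytokines Il1a (-2.48) and Il1b (-2.02), the chemokine Ccl3 (-2.10), Acod1 (-2.09), the lectin Clec4e (-1.94), the neutrophil protein S100a8 (-1.90), the macrophage elastase Mmp12 (-1.78), haptoglobin, Hp (-1.77), and the zinc transporter Slc30a2 (-1.74). The largest positive ones included Cyp2c55 at 2.88, Cyp4f14 at 2.55, the water channel Aqp8 at 2.46, Dpep1 at 2.46 and Fa2h at 2.21, with the B cell genes Ms4a1 (2.65), Cr2 (2.33) and Bank1 (2.33) and the MHC class II gene H2-DMb2 (2.19). The X-inactivation transcript Xist was higher by 2.99, and the Y-linked Uty (-1.03), Kdm5d (-0.91) and Eif2s3y (-0.66) were lower.

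The neutrophil list had a median of -1.12, with 10 of 14 genes lower by 2-fold or more. Of its genes 13 were lower and 1, Ly6g, was higher in the F/F tumour. In wild-type mice Ly6g hardly differed between tumour and normal colon (-0.04). Cytokines and chemokines had a median of -0.92. Wnt targets were lower by a median of -0.51, with the stem cell factor Ascl2 at -1.02, stem cell genes by -0.48, Paneth cells by -0.40, ribosome biogenesis by -0.31, with Rrs1 at -0.40, G2/M and mitosis by -0.22, with Kif20a at -0.46, G1/S by -0.15, with Gins1 at -0.56, and macrophages by -0.17, with Arg1 at -0.93. The G1/S percentile of 1.78 became 3.32 with the mean of the probe sets, where the list no longer stood apart. Cdk1 was lower by -0.29. Colonocyte genes had a median of 0.95, with 13 of 28 higher by 2-fold or more, B and plasma cells 0.95, neurons and glia 0.66, with Scn7a at 1.31, smooth muscle 0.53, with Des at 0.96, tuft cells 0.51, with Rgs13 at 1.46, and ion transport 0.51, with the anion exchanger Slc26a3 at 2.12. Rgs13 lay below the level filter in both the wild-type (3.16) and the F/F tumour (4.62), so its difference is uncertain. Smaller medians were those of adipocytes (0.47), enteroendocrine cells (0.37, Gcg at 1.27), fatty acid oxidation (0.36), T and NK cells (0.30, Cd4 at 1.21), goblet cells (0.29, Retnlb at 1.84), MHC class II (0.27) and oxidative phosphorylation (0.21). The squamous list was at -0.36 and, without the filter on level, at 0.013.

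In the iron list Tfrc (0.90) and Heph (0.90) were higher in the F/F tumour and the metalloreductase Steap4 (-1.03) and Cp (-0.90) lower, and the median of -0.08 lay at the 11.3th percentile. The JAK-STAT3 median was -0.09, at the 9.48th percentile and at the 0.03th without the filter; Hp and Saa3 (-1.58) were lowest and Fos (1.08) highest. Stat3 (-0.09) and Jak1 (0.10) differed little, and Cdx2 was higher by 1.39. In all 205 genes were higher and 61 lower by 2-fold or more, and the distal and proximal lists had medians of -0.16 and 0.08.

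Over both tissues, limma called 0 genes higher and 0 lower in F/F than in wild-type at an adjusted p under 0.05, with 589 higher and 402 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.506. No gene passed without the trend, with robust eBayes, without the filter or after cyclic loess. Tfrc had a genotype difference of 0.72 (SE 0.13, adjusted p = 0.523), higher in both F/F arrays. Adjusted over the list alone, 6 cytokine and chemokine genes, 2 genes each of Paneth cells, macrophages and interferon response and 1 each of Wnt targets and JAK-STAT3 were lower in F/F. By the same adjustment 5 adipocyte, 5 fatty acid oxidation, 3 proximal, 2 goblet cell genes and 1 colonocyte gene were higher, and no iron gene passed (smallest adjusted p = 0.055). These counts have no adjustment across the lists and do not measure the spread between animals, so they describe these arrays only. The genotype differences in the 2 tissues correlated across genes with Pearson's r of 0.147 and Spearman's rho of 0.172. There were 13 genes higher by 2-fold or more in both tissues against 1.5 for independent lists, 5 lower in both against 0.6, and 8 in opposite directions against 2.3. The 5 lower in both, 4 of them chosen after their values were seen, were Slc30a2, the chemokine Cxcl5, Lilrb4a, the amino acid transporter Slc38a4 and Vmn1r157.

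**Figure D3:**
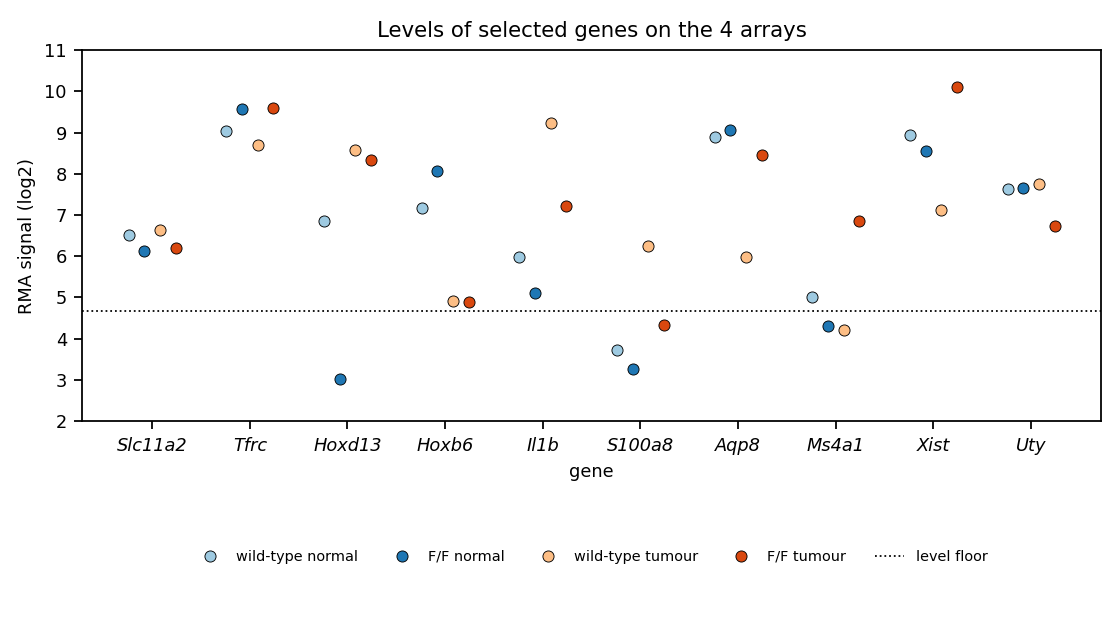
RMA signal (log2) of 10 genes on the 4 arrays, 1 point per array, with the level used as the filter (4.67) as a dotted line. Slc11a2 is lower and Tfrc higher in both F/F arrays, Hoxd13 is below the line in F/F normal colon alone (3.02), and Xist is highest (10.1) where Uty is lowest (6.72), in the F/F tumour.

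The difference between the tumour effects of the 2 genotypes asks where tumour minus normal differs between them, be it through the tumour or the normal arrays. With 4 arrays it has no residual and was not tested. It was largest in Hoxd13 (3.61), Xist (3.40), Ms4a1 (3.35), Tgm3 (3.33) and Pla2g4c (3.28), and lowest in Mptx2 (-3.99), Hp (-2.41), Car3 (-2.32), Ces1g (-2.19) and Sis (-2.02). B and plasma cells (median 1.48), smooth muscle (1.13), colonocytes (0.82), distal position (0.80), MHC class II (0.71) and fibroblasts (0.52) stood above random lists, as did neurons and glia (0.78), tuft cells (0.59), ion transport (0.54), goblet cells (0.26), endothelium (0.24), macrophages (0.20) and Paneth cells (0.20). Neutrophils (-1.04), proximal position (-0.87), cytokines (-0.51), adipocytes (-0.50), Wnt targets (-0.32) and stem cells (-0.38) stood below. G2/M (-0.09), G1/S (-0.18), iron transport (-0.14) and JAK-STAT3 (0.03) did not stand apart. Hoxd13, Tgm3, Pla2g4c, Car3, Ces1g and Sis differed more between the normal arrays than between the tumours. Several list medians did so too: distal position (-0.88 between the normal arrays, -0.16 between the tumours), proximal position (0.80 and 0.08), fibroblasts (-0.40 and -0.07), macrophages (-0.41 and -0.17) and Paneth cells (-0.51 and -0.40). Adipocytes (0.86 and 0.47) and endothelium (-0.16 and 0.10) did likewise. For all of these the value does not show a change in the tumour. Smooth muscle (-0.58 and 0.53) and MHC class II (-0.27 and 0.27) differed by similar sizes in opposite directions, so their values come from both tissues. Others, such as neutrophils (-0.16 and -1.12), differed more between the tumours. In all 346 genes had a difference of 1 or more and 162 of -1 or less.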

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

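The tests of position along the colon, that of normal colon of the position on the normal arrays, and the values of escape genes among random sets and in normal colon were chosen after the result was seen; the other tests of tissue admixture and of sex-linked genes were chosen before, except that the demand that admixture be excluded with both normal arrays was added after the colonocyte result was seen. The differences between 2 arrays given here were not tested, since each rests on 1 array per group. Limma's additive model, which tests what both genotypes or both tissues share, called none of St8sia5, Xist, Atp12a and Tgm3. Genes picked for opposite directions add to that model's only residual term, so this says little about them. Bootstrap intervals here and below resample genes on these arrays, so they show spread across genes and not between animals.

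Some genes and lists moved in opposite directions in the groups compared. St8sia5 differed between tumour and normal colon by -1.24 in wild-type and 1.98 in F/F mice, and between F/F and wild-type by -2.05 in normal colon and 1.17 in tumour. Xist differed between tumour and normal colon by -1.84 in wild-type and 1.55 in F/F mice. Between F/F and wild-type, the proton pump gene Atp12a differed by -1.51 in normal colon and 1.35 in tumour, and the transglutaminase Tgm3 by -1.91 and 1.42. The B and plasma cell median was -0.53 in normal colon and 0.95 in tumour, that of MHC class II -0.27 and 0.27, that of smooth muscle -0.58 and 0.53, and that of squamous epithelium 0.40 and -0.36. Without the filter on level the squamous median in tumour was 0.013, so its opposite direction depends on the filter. Among 7321 probe sets at or above the level filter that the annotation leaves unnamed, which no comparison used, 172 were higher and 86 lower by 2-fold or more in tumour in both genotypes.

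Genes of position differed between the normal arrays, with posterior Hox genes lower and proximal genes higher in F/F. Normal tissue from different positions along the colon stays open and cannot be told apart from other causes. Across 21 Hox genes the difference had a rho of -0.527 with paralog number, but 7 of the genes of paralogs 9 to 13 are the distal list itself. The 13 Hox genes outside the position lists gave -0.030 (95% bootstrap interval -0.62 to 0.63). Only 2 of these 13 are of paralogs 9 to 13, so this value could hardly show a gradient and does not count against position. Between the tumour arrays the distal list was at -0.16 (-0.23 to 0.21). For these arrays only, that goes against a Dmt1 effect on these genes in any colon tissue, and an effect in normal colon alone stays open. Different shares of muscle wall cannot be told apart from different positions, because the proximal list lay 0.61 above the colonocyte list with an interval that includes 0 (-0.07 to 1.18). The labels do not give the position of any piece.

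In the F/F tumour, most colonocyte genes were higher and most neutrophil and cytokine genes lower than in the wild-type tumour. A candidate explanation is more normal colon in the F/F piece. That share, computed from the wild-type tumour and normal levels, would be 34.3% for Wnt targets (interval 31.4 to 39.4) and 72.7% for neutrophil and cytokine genes (65.6 to 84.2), and the gap of 38.4 points (28.3 to 50.6; 35.2, 24.1 to 46.6, with F/F normal colon) argues against admixture as the whole cause for the latter. For colonocyte genes (48.5%, 37.0 to 82.1) the gap was 14.2 points (1.5 to 48.2), which the test had set as its exclusion, but with F/F normal colon it was 6.1 (-8.2 to 17.7), so the exclusion set on 1 array was too strict. Proximal genes and Hox paralogs 1 to 8 needed a share that differed from that of the colonocyte genes by -40.7 points (-74.8 to -5.6, 9 genes). With F/F normal colon the gap was -38.2 (-47.7 to -12.8, 12 genes). The proximal list by itself needed 7.9% (0.8 to 49.3) and 2.4% (0.3 to 46.4), which decides nothing. The gap therefore leans on a few Hox genes, which may not move independently. It goes only weakly against normal colon of the position on the normal arrays as the cause for the colonocyte genes. Normal colon of a more distal position and a change in the tumour cannot be told apart there, because no array holds such tissue, and a Dmt1 effect on inflammation stays open and untested.

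Xist and Y-linked genes moved apart between the tumours. Xist was at log2 7.11 in the wild-type and 10.1 in the F/F tumour, and Uty at 7.76 and 6.72, while all 4 arrays showed both well above the level filter, as RNA from several animals of both sexes would. The X-linked genes known to escape inactivation, Kdm6a (0.29), Kdm5c (0.14), Ddx3x (0.055) and Pbdc1 (0.054), differed by small amounts (Eif2s3x was chosen too but was not among the kept genes), and their median lay above that of 343 other X-linked genes by 0.12 (interval 0.05 to 0.31), where the test had set an interval above 0 as its support. Random sets of 4 other X-linked genes had an SD of 0.15 and placed this at the 78.7th percentile, and Kdm6a was higher in normal colon too, by 0.24. The support set on the interval was therefore too weak, and these 4 genes alone cannot tell a larger share of RNA from females apart from other causes. Xist (2.99), Uty (-1.03), Kdm5d (-0.91) and Eif2s3y (-0.66) themselves moved between the tumours in the directions that such a share would give. In normal colon they differed by -0.40, 0.04, -0.16 and -0.001. Within F/F mice, tumour against normal colon gave 1.55 for Xist, -0.935 for Uty, -0.974 for Kdm5d and -0.645 for Eif2s3y. Within wild-type mice the values were -1.84, 0.135, -0.22 and 0.018. No biological explanation was tested, and sex could contribute to any difference between the tumours. It could also contribute to tumour against normal colon within a genotype, to the difference of the tumour effects and to limma's residual.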

How the results depend on the processing

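No paired analysis was possible because the labels give each group 1 replicate, beyond the genotype term of limma's model, which already sets tumour against normal colon within each genotype. With 1 array per group no array could be left out in turn. The alternative baselines were chosen after seeing the data; the other settings were not. Of the values under these settings, 77 counts stayed within 1.5 times and 19 moved further; 3267 values of single genes moved by less than the spread across genes and 24 by more; 1069 list medians moved by less than the spread of random lists, 105 by more and 1, of a list that stood apart, changed sign; 1307 list percentiles kept their side of the limits, 18 crossed outward, 19 inward and 1 to the other side. With lists that did not stand apart counted too, 30 list medians changed sign. Changed list values are named below only for iron transport, Wnt targets, G2/M, G1/S and JAK-STAT3 and for the list that turned. Other lists described as standing apart may not do so under every setting. No spread between replicates was available to set these against. At 1.5-fold and 3-fold, which count other sizes by construction, the tumour counts were 2055 and 309 higher and 1546 and 237 lower in wild-type, and 1764 and 261 higher and 1269 and 160 lower in F/F; the genotype counts were 449 and 13 higher and 482 and 20 lower in normal colon, and 646 and 48 higher and 347 and 11 lower in tumour. With wild-type normal colon as baseline 253 genes were lower in F/F tumour, against 460. For the difference of the tumour effects, 251 genes were lower with no filter and 105 with the filter on the mean, against 162. Limma's count of genes lower in F/F at an unadjusted p under 0.05 was 643 over the 22180 genes without the filter, against 402. Other counts, limma's adjusted ones included, stayed within 1.5 times.

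Without the filter on level, the Wnt median was 2.29 in wild-type and 1.69 in F/F tumour against normal colon and -0.43 between the tumours; the iron median in normal colon was 0.088 (percentile 81.7, against 99.9); the JAK-STAT3 median was -0.19 between the tumours (percentile 0.03, against 9.48) and -0.046, against 0.03, for the difference of effects, where it stood apart in neither; and the squamous list turned from -0.36 to 0.013 between the tumours (percentile 61.7, against 2.11). With the filter on the mean, the Wnt median was 2.44 in F/F tumour. With the mean of the probe sets, the Wnt medians were 2.22 and 1.66 in tumour, -0.052 in normal colon between genotypes (percentile 6.88, against 0.40) and -0.39 between the tumours, and G1/S between the tumours lay at percentile 3.32, against 1.78. Without shared members the Wnt medians were 2.57 in wild-type tumour and -0.38 between the tumours. After quantile normalization the iron median in normal colon was 0.15, that of G2/M -0.19, and the Wnt percentile 3.71. Centring moved the wild-type tumour medians of iron to 0.027, of G2/M to 0.50 and of G1/S to 0.47, by the shift of all genes. Apart from that shift and the change of members without the filter, the cause was not tested. Signal near the filter limits the differences: 12 of the 20 named genes had an array below it in each tumour comparison, and 7 of 20 in each genotype comparison.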

Other observations

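B cell and plasma cell genes parted within their list, a split made after the values were seen. The 9 B cell members differed between F/F and wild-type tumour by a median of 1.58, from 0.71 to 2.65, and the 5 plasma cell members by 0.10, from -0.06 to 0.37. In normal colon the medians were -0.48 and -0.98. Of the exocrine pancreas list 3 genes were kept: Pnliprp1 was higher in tumour by 4.90 and 5.90, Cela1 by 0.15 and 1.83, and Clps differed by 0.35 and -0.06, in wild-type and F/F mice. No gene of the erythroid list was kept (0 genes).

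The 13 genes higher by 2-fold or more in F/F in both tissues include the clock genes Dbp (1.05 in normal colon, 1.58 in tumour) and Nr1d1 (1.31 and 1.57), both named after their values were seen. The hypothesis that the F/F and wild-type arrays differ in clock phase was then tested on other clock genes, chosen before their values were seen. Per2, Tef, Hlf and Bhlhe41 were chosen too but were not among the kept genes. Per1, Per3, Nr1d2 and Ciart, which peak near Dbp, were higher in F/F by 0.76, 0.64, 0.75 and 0.81 on average over the tissues, and Arntl, Npas2, Clock, Cry1 and Nfil3, which peak in the opposite phase, differed by -0.52, -0.12, -0.22, 0.03 and -0.48. The difference of the medians was 0.98 (95% bootstrap interval 0.73 to 1.29), above all 10000 differences of random sets matched on level, consistent with a difference in phase. Another hour of collection and an effect of Dmt1 on the clock were not tested against each other, since the hour is not given in the sources used here.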
